A study of Homo sapiens with 4 samples.

How the data were processed

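The study measured mRNA in HCT116 colon carcinoma cells without their own p53, infected with p53-V272M or p53-R282W, each untreated or with ATO at 1 µg/ml for 24 h. Libraries were made with a TruSeq RNA kit and sequenced as paired ends on an Illumina HiSeq instrument, per the labels' protocols. FastQC, cutadapt, STAR and the hg38 build are named, per the submitters' processing notes, with no versions. The quantification tool, the annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes cannot be separated. Other named genes with at least 10% of exonic bases, over all annotated transcripts, in exons of another compared gene are DBP (10.1%, SPHK2), HMSD (12.7%, SERPINB8), SLC25A21 (13.0%, PAX9), FOXM1 (15.9%, ITFG2) and KRT18 (16.3%, KRT8), which are uncertain in the same way as those given as uncertain beside their values. The deposited values are a length-normalised signal per gene, with 2 decimals, whose unit the sources do not name, and FPKM and TPM could not be told apart. They are not read counts. Protein-coding genes only are in the table, 19752 of them, and 0 columns of other samples.

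All 19752 gene IDs matched GENCODE release 29 on GRCh38, which gave symbols and coordinates by gene ID. The deposited symbol differed from it for 28 genes, of which 27 were whole numbers in place of a name. Relative depth was read from low values of genes with 1 annotated transcript shorter than 1400 bases, where a value should be a whole number of fragments times a step divided by the transcript length less an offset. The best steps had offsets of 205, 200, 200 and 200 bases for V272M untreated, V272M ATO, R282W untreated and R282W ATO. They made 82.0%, 87.0%, 82.2% and 81.8% of 111, 230, 152 and 165 low values whole within rounding, against 24.3%, 23.5%, 25.7% and 24.1% by chance. If the values are TPM, the step also depends on which transcripts a library holds, so these depths are approximate. Since most genes have several transcripts, counts were not recovered, and no counting interval is given.

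Genes with a value of at least 1 in at least 1 library were compared (11922). Ratios are differences of log2(value + 1). With 1 library per group, each line's ATO ratio and each ratio between lines was compared with a 2-fold rule and has no test and no p-value. The only test was limma (version 3.58.1, R 4.3.3, with the mean-variance trend) on log2(value + 1) of all 4 libraries, with ATO and line as terms, 1 residual degree of freedom and 6.26 prior degrees of freedom, and Benjamini-Hochberg adjustment. Nothing in the labels says that the cultures were independent repeats, so its p-values hold no replicate error of either line. The error of a gene combines how the lines differ in its response with a variance estimated over all genes. The latter, with the prior degrees of freedom, weighs more. Genes are said to rise or fall only where this test gave an adjusted p under 0.05. Gene lists were described by the percentile of their median among 10000 random lists of equal size matched on mean expression in 20 bins. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used. A gene was called sequence-sharing where at least 20% of the 50-base tiles of its longest transcript, taken every 25 bases, occurred in another protein-coding gene, which held for 754 compared genes.

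The groups, the tests, the alternatives, the 19 gene lists and the rule for named genes were fixed before the data were examined. The rule names the 10 highest and 10 lowest genes by the smaller of the 2 ATO ratios among genes 2-fold the same way in both lines, the 5 highest and 5 lowest per line, the 10 highest and 10 lowest between untreated lines, and the 5 highest and 5 lowest by the difference of ATO ratios among genes 2-fold in a line. It adds up to 4 members of each list and 9 genes known to respond to p53, metal or stress. A named gene needs a value of at least 2 in its higher library and is not a clone-named, non-coding or Y-linked gene. Some items that the rule names are not reported here. Alternatives were median-ratio scaling, no filter, a filter of 5, a pseudocount of 0.1, thresholds of 1.5-fold and 4-fold and a fit without the line term, and, added after seeing the data, the removal of sequence-sharing genes and a fit without the variance trend.

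The steps were tested on simulated data. For ATO over both lines and a noise of SD 0.1 on the log2 scale, limma on 11793 simulated genes with 200 changed recovered 100% of those changed 2-fold and 100% of those changed 4-fold, and 13.4% of its 231 calls were false, more than the nominal 5%. The real difference of ATO ratios between the lines had an SD of 0.272, against 0.198 in that simulation. With a noise of SD 0.136, which gave 0.257, limma on 11814 simulated genes also recovered 100% of those changed 2-fold and 100% of those changed 4-fold, with 6.1% of 213 calls false. In both simulations each changed gene changed equally in the 2 lines. Smaller changes, changes unlike between the lines and more than 200 changed genes were not simulated. Recovery and false calls for those are not known. The count of 2-fold genes for ATO in V272M cells recovered 200 of 200 changed genes among 11922. These were set 4-fold higher on the ratios themselves, with noise far smaller than the change, so full recovery was certain. That run checks the counting step only and does not show how many real 2-fold genes are missed.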

Results

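RNA was sequenced from HCT116 cells, a human colon carcinoma line, whose own p53 had been knocked out and which were infected to express 1 of 2 p53 proteins with a single amino acid change, V272M or R282W. Each line was sequenced untreated and after 24 h with arsenic trioxide (ATO) at 1 µg/ml, which gives 4 libraries and 1 library per group. There were no replicates, so no value below has a replicate error. The sources used here give no time for the untreated cultures. The deposited table held 1 length-normalised expression value per gene and library for 19752 protein-coding genes. The values of a library summed to 639194 in untreated V272M cells, 656504 in V272M cells with ATO, 633156 in untreated R282W cells and 629903 in R282W cells with ATO. Genes at a value of 1 or more numbered 11637, 11557, 11598 and 11483 in the same order, and 11922 genes reached 1 in at least 1 library and were compared. Low values fell on steps that put the depth of the libraries, relative to the deepest, at 100%, 78.2%, 95.2% and 87.8%. A value of 1 on a transcript of 2000 bases then stood for about 76, 60, 72 and 67 fragments, so the low values carry the most counting error. Folds are ratios of deposited values, and log2 ratios are differences of log2(value + 1), which are smaller than the fold for genes near 0.

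The title of the series names rescue of mutant p53 by ATO, so the first question is what the drug did to p53 target genes in each line. A library from cells without any p53 was not analysed here.

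In V272M cells the p53 target genes were higher with ATO as a group. Of the 46 members of the list that were compared, 43 had a log2 ratio above 0 and 14 were at least 2-fold higher, and the median log2 ratio was 0.66. That median lay at percentile 100 of 10000 random lists matched on expression, whose central 95% ran from -0.14 to 0.05. CDKN1A (chromosome 6, 36676460 to 36687339, plus strand), the p21 inhibitor of cyclin-dependent kinases, went from 31.04 to 162, which is 5.23-fold. MDM2 (chromosome 12, 68808176 to 68850686, plus strand), the ubiquitin ligase that degrades p53, went from 67.4 to 278, which is 4.13-fold. FAS, a death receptor, was 4.63-fold higher and BTG2, an antiproliferative gene, 4.37-fold higher. The BH3-only genes BBC3 (PUMA) and PMAIP1 (NOXA) were 1.96-fold and 1.52-fold higher.

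In R282W cells the same 46 genes had a median log2 ratio of 0.04 with ATO, at percentile 94.5 of the random lists and so inside their central 95%. After median-ratio scaling that median was 0.08, and without the filter on low values 0.02, both inside the central 95%. Of the 46 genes 26 were above 0 and 2 were at least 2-fold higher, GDF15 and SESN2. SESN2 is also a member of the list of ATF4 targets described below. CDKN1A was 1.55-fold higher (25.97 to 40.32), MDM2 1.35-fold higher (72.3 to 97.7) and FAS 1.67-fold higher. BTG2 had 6.03 untreated and 3.76 with ATO. BBC3 was 1.59-fold and PMAIP1 1.37-fold higher. GDF15, a secreted stress cytokine, was 6.41-fold higher in V272M and 5.52-fold in R282W cells, and SESN2 1.75-fold and 2.64-fold.

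**Figure D1:**
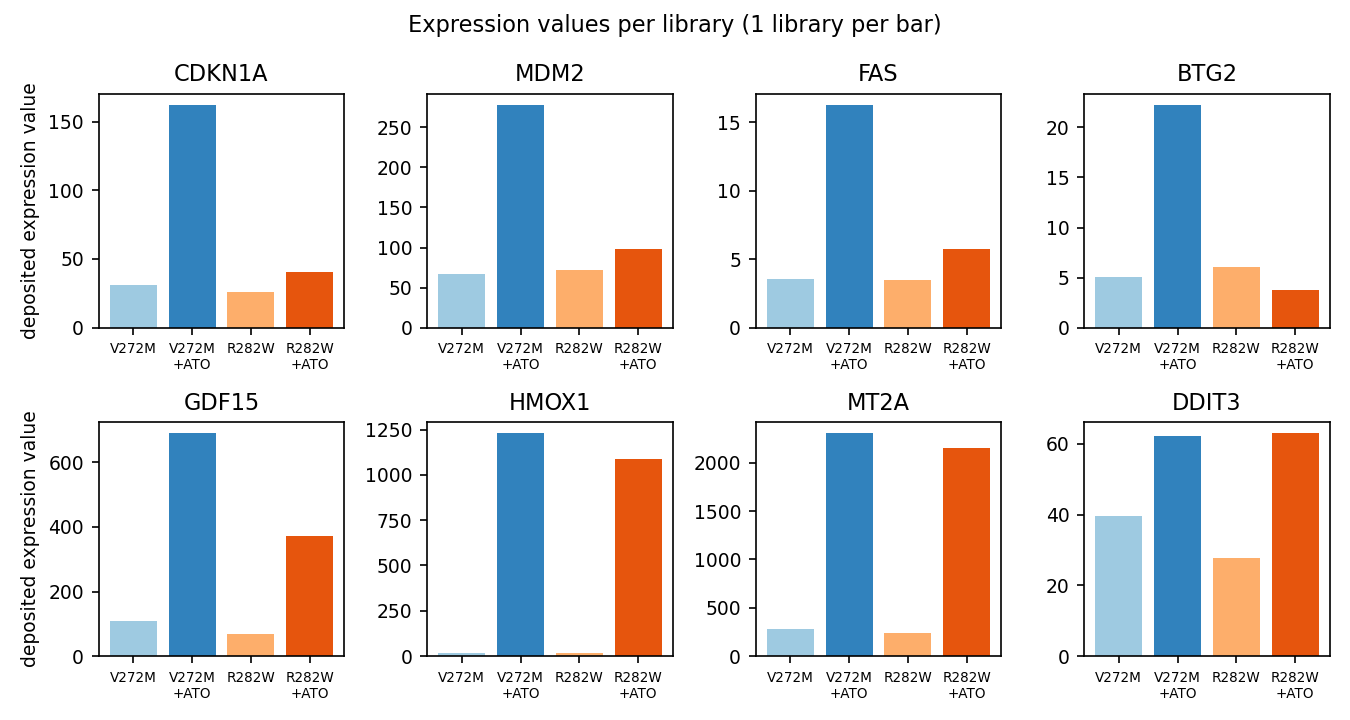
Deposited expression value (linear axis from 0, length-normalised) of 8 genes in the 4 libraries, 1 library per bar and therefore no error bar. GDF15, HMOX1 and MT2A were higher with ATO in both lines by similar folds, while CDKN1A reached 162 in V272M cells and 40.32 in R282W cells with ATO.

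Set side by side, 43 of the 46 p53 targets had the larger ATO log2 ratio in V272M cells, with a median difference of 0.55 (percentile 100 of random lists). The 13 mitochondrially encoded genes were also all larger in V272M cells, with a median difference of 0.51 (percentile 100), and the V272M ATO library had the lowest depth, the fewest genes listed at 0 (2838) and the most olfactory receptor genes above 0 (184 of 380). For CDKN1A that difference was 1.74, for MDM2 1.60 and for FAS 1.33, whereas the absolute difference of ATO log2 ratios was under 0.53 for 95% of all compared genes. With limma over both lines, 18 of the 46 targets rose, 1 fell (KITLG) and 27 did not pass, and 19 rose and 1 fell when adjusted over the list alone. CDKN1A (adjusted p = 0.0181), MDM2 (0.0252), FAS (0.0155), BBC3 (0.00349) and PMAIP1 (0.00411) passed, and BTG2 (0.319) did not. Most of the error in that test is estimated over all genes, so passing does not show that the lines responded alike. This design has no test of the difference between the lines, since each ratio rests on 1 library per group.

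Both lines shared a large response of metal and oxidative stress genes. HMOX1 (chromosome 22, 35380361 to 35394214, plus strand), the heme oxygenase, went from 14.30 to 1230 in V272M cells and from 14.78 to 1086 in R282W cells, 86.0-fold and 73.5-fold (limma adjusted p = 2.543e-08). The metallothioneins, small metal-binding proteins, rose with it. MT2A was 8.33-fold higher in V272M and 8.94-fold in R282W cells, MT1X 7.48-fold and 6.71-fold, and MT1E 6.49-fold and 5.99-fold. All 5 compared members of the metallothionein and metal response list, among them the zinc exporter SLC30A1 (2.16-fold and 2.03-fold), rose in limma and none fell, also when adjusted over the list alone, with list medians of 2.69 and 2.58. Without the filter on low values, where 7 of the 10 members of the list were compared, these medians were 1.01 and 1.12. Of the 27 compared targets of NRF2, the transcription factor of the antioxidant response, 24 rose, 0 fell and 3 did not pass, and 24 rose and 1 fell adjusted over the list alone. Their medians were 1.01 and 0.89, and the median difference between the lines was 0.00. GCLM, a subunit of the enzyme that starts glutathione synthesis, was 4.75-fold and 4.81-fold higher, and SLC7A11, the cystine transporter, 3.17-fold and 4.05-fold. TRIM16L was 3.62-fold and 5.48-fold higher, but 56.4% of its transcript's sequence tiles occur in another gene, so its value is uncertain.

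**Figure D2:**
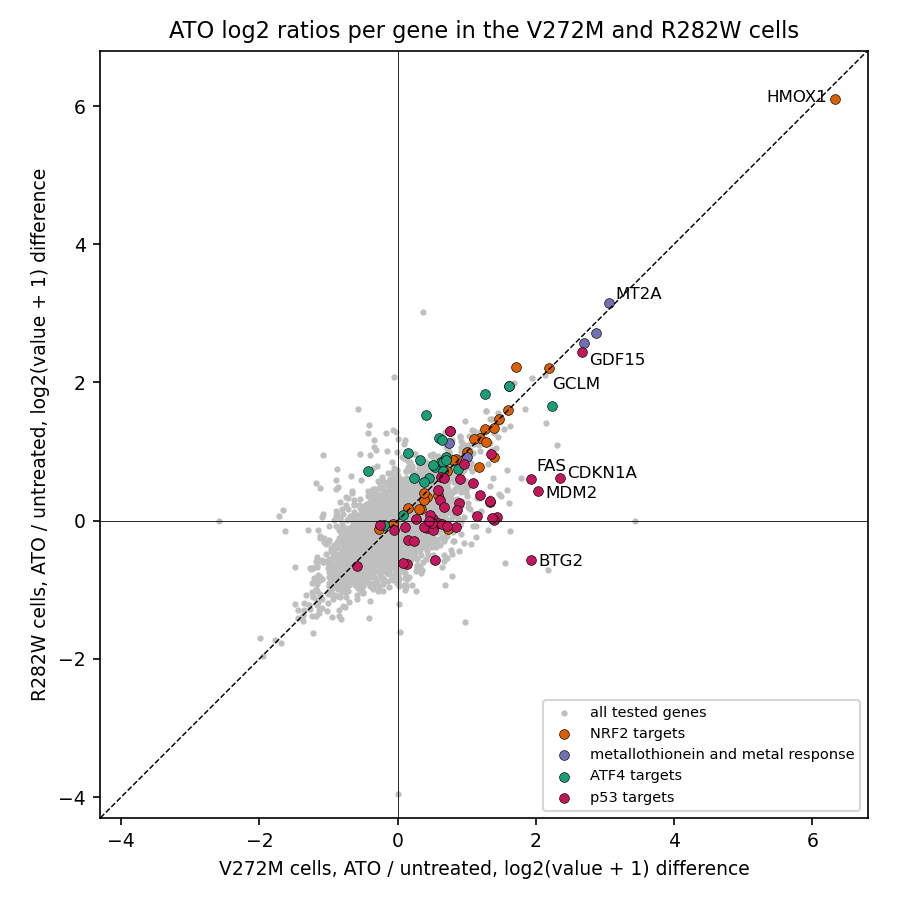
ATO log2 ratio of each compared gene in V272M cells (x axis) against R282W cells (y axis), as differences of log2(value + 1), with the dashed line marking equal ratios and a gene on more than 1 list in the colour of the list drawn last. NRF2 targets and metal response genes lie along that line up to HMOX1 at 6.33 and 6.11, and many p53 targets lie below it, among them CDKN1A at 2.35 and 0.61.

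Targets of ATF4, the transcription factor of amino acid and integrated stress, also rose. In limma 20 of 23 rose, 0 fell and 3 did not pass, with the same counts adjusted over the list alone. Their median log2 ratio was 0.59 in V272M and 0.85 in R282W cells, and 2 of the 23 had the larger ratio in V272M cells. TRIB3, a pseudokinase, was 2.42-fold and 3.63-fold higher, DDIT3 (CHOP) 1.57-fold and 2.28-fold, and NUPR1 8.80-fold and 8.16-fold. The folds of NUPR1 rest on untreated values under 1, since it went from 0.91 to 8.01 and from 0.43 to 3.51. Its log2 ratios were 2.24 and 1.66. Without drug the ATF4 targets were lower in R282W than in V272M cells by a median log2 ratio of -0.30 (percentile 0 of random lists), and with ATO the median between the lines was 0.03. CHAC1, a glutathione-degrading enzyme, had 31.11 and 15.24 untreated and 41.71 and 46.06 with ATO. DDIT3 is uncertain, since 27.2% of its exonic bases overlap exons of MARS on the opposite strand.

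Across all 11922 genes, 103 were at least 2-fold higher and 80 at least 2-fold lower with ATO in V272M cells, and 82 and 70 in R282W cells. In both lines 49 were higher and 35 lower, where independent lists would share 0.71 and 0.47, and 0 went 2-fold in opposite directions. Those comparisons share no library. With a pseudocount of 0.1 the totals were 438 and 417 in place of 183 and 152, and 174 in place of 84 for both lines. Across genes, which are not independent replicates, the ratios of the lines correlated with Pearson's r = 0.693 and Spearman's rho = 0.675. Besides the genes above, the highest in both lines were ZNF469 (6.93-fold and 7.25-fold) and UPP1, the uridine phosphorylase (3.93-fold and 4.27-fold). With limma, blocked on line, 3092 genes passed an adjusted p of 0.05, of which 1149 rose and 1943 fell. After median-ratio scaling 1412 rose and 1377 fell, so the balance of directions rests on the scaling. The error of this test combines how unlike the lines responded, with 1 residual degree of freedom, and a variance estimated over all genes. The latter has 6.26 prior degrees of freedom and weighs more. A gene with unlike ratios in the lines can therefore pass. The limma count dropped to 1629 without the variance trend and to 0 without the filter on low values, where 4338 genes had an unadjusted p under 0.05.

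The genes with the lowest ratios in both lines fell in limma. DBP and PER2, components of the circadian clock, were at 0.230 and 0.266 of the untreated value in V272M cells and at 0.225 and 0.245 in R282W cells, and PER1 at 0.355 and 0.352. RAB26, a small GTPase, was at 0.193 and 0.245, the phosphatase CTDSP1 at 0.276 and 0.283, the Wnt ligand WNT16 at 0.295 and 0.277, and SAMD13 at 0.311 and 0.317. SOX4 was at 0.375 and 0.377 and PRKACB, a catalytic subunit of protein kinase A, at 0.362 and 0.404. The highest limma adjusted p among them was that of PER2 (8.557e-04). In the cholesterol synthesis list 14 of 20 members fell, 0 rose and 6 did not pass, and 17 fell adjusted over the list alone. Its medians were -0.32 and -0.30, with LSS, the lanosterol synthase, at 0.394 and 0.390, INSIG1 at 0.558 and 0.539 and MVD at 0.670 and 0.641.

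G1/S genes, which act in DNA replication, had lower values with ATO in both lines. Of 30 G1/S genes 14 fell, 0 rose and 16 did not pass in limma, and 19 fell adjusted over the list alone. Their median was -0.47 in V272M cells (percentile 0) and -0.15 in R282W cells (percentile 0.8), and 1 of the 30 had the higher ratio in V272M cells. MCM7, part of the replicative helicase, was at 0.355 and 0.432 of its untreated value, E2F1 at 0.480 and 0.663, FEN1 at 0.544 and 0.688 and CCNE2, of which 37.0% of exonic bases overlap INTS8 on the opposite strand and which is uncertain, at 0.598 and 0.699. Of 30 G2/M genes 4 fell, 0 rose and 26 did not pass, and 4 fell adjusted over the list alone. The G2/M medians were -0.14 (percentile 3.25) and 0.02 (percentile 84.2), both inside the central 95% of random lists, although 1 of the 30 had the higher ratio in V272M cells and the median difference of -0.16 lay at percentile 0. CDK1 was at 0.740 and 0.776 and BIRC5 at 0.752 and 0.882 of the untreated value. FOXM1, at 0.720 and 0.931, did not pass (limma adjusted p = 0.0569).

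**Figure D3:**
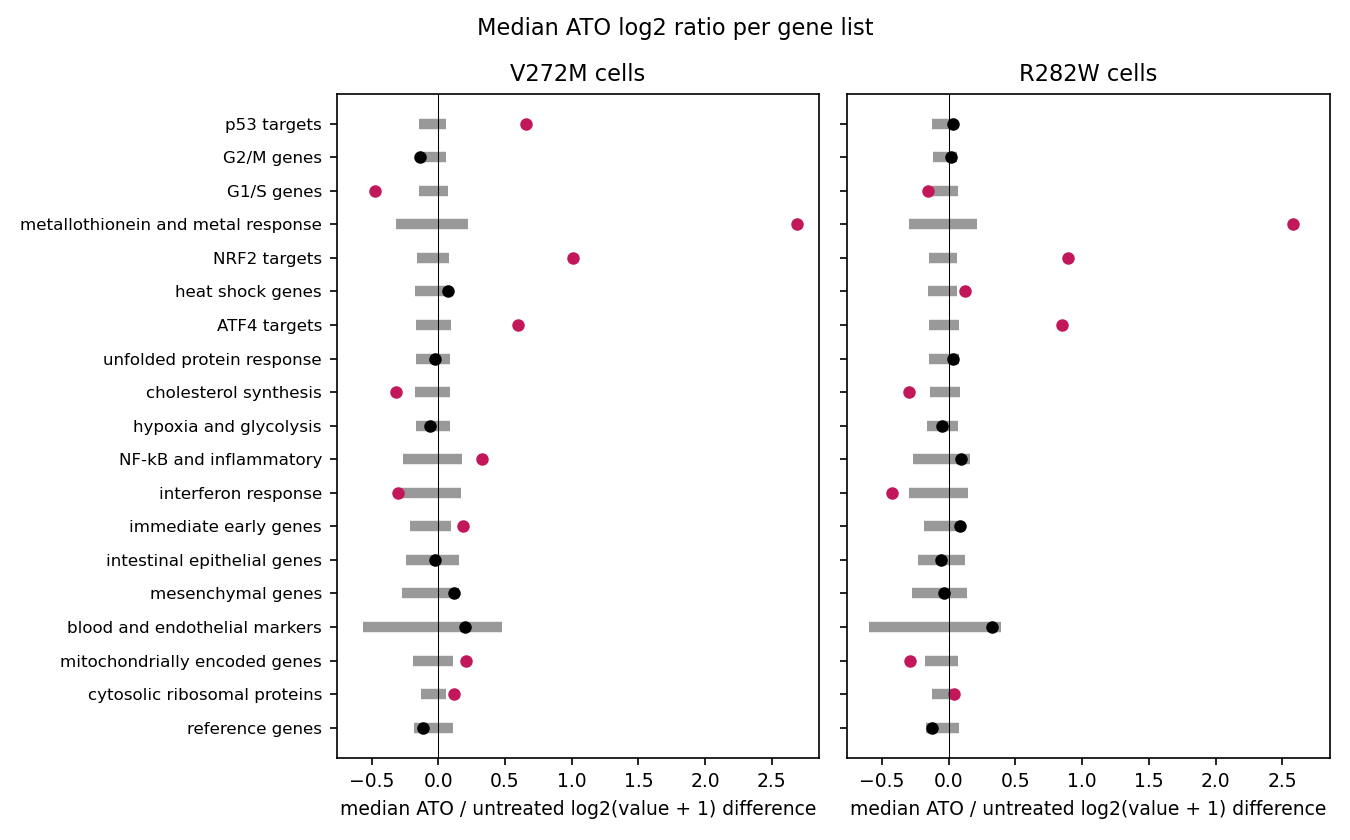
Median ATO log2 ratio, as a difference of log2(value + 1), of the 19 gene lists in V272M cells (left) and R282W cells (right), with grey bars for the central 95% of 10000 expression-matched random lists and coloured points for medians outside them. The p53 targets stood at 0.66 in V272M and 0.04 in R282W cells, while metal response and NRF2 genes were high in both.

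Further stress and signalling lists were compared. Of 19 heat shock genes 6 rose, 0 fell and 13 did not pass (7 rose and 2 fell adjusted over the list alone), with medians of 0.08 and 0.12. The V272M median lay inside the central 95% of random lists, and without the filter it was 0.09 and outside. HSPA8 was 1.53-fold and 1.24-fold higher, BAG3 1.46-fold and 1.40-fold and DNAJB4 1.66-fold and 1.38-fold. HSPA1A, whose sequence is shared with HSPA1B, had 2.92, 5.33, 5.88 and 6.47 in the 4 libraries. Of 20 unfolded protein response genes 5 rose, 7 fell and 8 did not pass (6 and 7 adjusted over the list alone), with medians of -0.02, which turned positive after scaling, and 0.03. XBP1 and HERPUD1 were 1.41-fold and 1.33-fold higher in V272M cells and 1.71-fold and 1.51-fold in R282W cells, while the chaperones CALR and PDIA4 were at 0.675 and 0.687, and at 0.712 and 0.694. Of 24 hypoxia and glycolysis genes 2 rose, 6 fell and 16 did not pass, with the same counts over the list alone and medians of -0.06 and -0.05. ALDOC was at 0.409 and 0.366 and LDHA at 0.584 and 0.597, and VEGFA was 1.49-fold and 1.62-fold higher. Of 9 NF-kB and inflammatory genes 3 rose, 0 fell and 6 did not pass (4 rose over the list alone), with medians of 0.33 and 0.10, or 0.14 and 0.04 without the filter. NFKB2 was 1.70-fold and 1.53-fold higher, and LIF went from 9.96 to 18.50 and from 9.64 to 11.52. Of 18 immediate early genes 4 rose, 3 fell and 11 did not pass (4 and 4 over the list alone), with medians of 0.19 and 0.08. A filter of 5 brought the V272M median to 0.11 and inside the central 95%. A pseudocount of 0.1 brought the R282W median to 0.15 and outside the central 95%. DUSP5 was 1.84-fold and 1.73-fold higher and FOSL1 1.53-fold and 1.52-fold, while KLF2 was at 0.411 and 0.606. Of 11 interferon response genes 5 fell, 0 rose and 6 did not pass, with the same counts over the list alone and medians of -0.30 and -0.42. Without the filter these medians were -0.12 and -0.07, the latter inside the central 95% of random lists, and with a filter of 5 they were -0.46 and -0.52. ISG15 was at 0.563 and 0.488, and IFIT1, with at most 2.60, at 0.205 and 0.273.

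Lists that describe cell type, and lists that describe the libraries, were also compared. Of 9 intestinal epithelial genes 3 rose, 1 fell and 5 did not pass, with the same counts over the list alone and medians of -0.02 and -0.06, which became 0.08 and 0.11 with a filter of 5, so neither has a fixed sign. The keratins KRT18 and KRT8 were 1.74-fold and 1.34-fold higher in V272M cells and 1.59-fold and 1.24-fold in R282W cells, while KRT19 was at 0.851 and 0.628. Of 13 mesenchymal genes 3 rose, 1 fell and 9 did not pass (4 and 2 over the list alone), with medians of 0.12 and -0.04, the latter of no fixed sign across settings. CYR61, a matricellular protein gene, was 1.69-fold and 1.61-fold higher. ACTA2, smooth muscle actin and not past the test (adjusted p = 0.168), was 4.30-fold higher in V272M cells and at 0.827 in R282W cells. It is uncertain, since 12.8% of its exonic bases overlap exons of FAS on the opposite strand and the use of strand is not known. Only 3 of 18 blood and endothelial markers reached a value of 1, with medians of 0.20 and 0.33 (0.01 and 0.01 without the filter) and a maximum of 7.11 for CD68, and 1 rose, 1 fell and 1 did not pass (2 and 1 over the list alone). Of 34 cytosolic ribosomal protein genes 3 rose, 0 fell and 31 did not pass, with the same counts over the list alone and medians of 0.12 and 0.04. RPL3 was 1.23-fold and 1.16-fold higher. Of 15 reference genes 2 rose, 7 fell and 6 did not pass (4 and 8 over the list alone), with medians of -0.12 and -0.13. TUBB was at 0.706 and 0.780 and GUSB at 0.711 and 0.661. Of the 13 mitochondrially encoded genes 12 did not pass and MT-ND2 fell, with 0 passing over the list alone. Their medians were 0.21 in V272M and -0.29 in R282W cells. Their share of all values was 6.72% untreated and 7.39% with ATO in V272M cells, and 7.49% and 5.89% in R282W cells.

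Without drug, the comparison of R282W with V272M cells asks how the mutants differ at baseline, and few genes differed. Of 11922 genes 14 were at least 2-fold higher in R282W cells and 17 at least 2-fold lower, and 95% of genes differed by less than 0.34 on the log2 scale. Sequence shared with other genes affected 24 of those 31, and 7 remained without them. A filter of 5 left 15 genes and a pseudocount of 0.1 gave 113. IL6ST, the gp130 cytokine receptor, had 9.24 in V272M and 21.40 in R282W cells, LAMA2, a laminin chain, 1.46 and 5.30, and CDKL1, a kinase gene with 26.1% of its exonic bases over ATP5S on the opposite strand and so uncertain, 2.81 and 8.81. HMSD had 3.82 and 0.99. P2RX6 (0.01 and 1.30) and TMEM105 (1.94 and 0.33) were named after their values were seen, as was the locus AC073508.2 (1.03 and 0.00), which overlaps SMARCE1 and is uncertain. LUZP6 (33.00 and listed at 0), HIST2H2AA3 (5.13 and listed at 0), MAGEA2B (15.83 and 5.50), SLX1A (5.83 and 18.33), SLX1B (18.69 and 8.10), EIF3CL (0.74 and 4.38) and RGPD5 (1.08 and 3.78) share most of their sequence with other genes and are uncertain. Of the 19 lists 8 had a median log2 ratio between the untreated lines outside the central 95% of random lists. Besides the ATF4 targets these were the p53 targets with -0.07 (percentile 0.12), the ribosomal protein genes with -0.07 (0.09), the intestinal genes with -0.12 (0.44), the immediate early genes with -0.10 (0.65), the G2/M genes with 0.04 (98.96), and the mitochondrially encoded and heat shock genes with 0.17 and 0.13 (both 100). With 1 library per line such percentiles describe these libraries only. Without the filter the intestinal median was -0.01 and inside that range.

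With drug, 15 genes were at least 2-fold higher in R282W than in V272M cells and 34 at least 2-fold lower, of which 12 shared sequence with other genes. The total of 49 became 25 with a filter of 5 and 176 with a pseudocount of 0.1. The p53 targets had a median log2 ratio of -0.65 (percentile 0), with BTG2 at -2.29, CDKN1A at -1.98 and MDM2 at -1.50. They were 1 of 8 lists outside the central 95% of random lists. The G1/S, G2/M and heat shock genes had medians of 0.28, 0.22 and 0.13, all at percentile 100, the mitochondrially encoded and ribosomal protein genes -0.33 and -0.16, both at percentile 0, the NF-kB genes -0.27 (0.04), or -0.11 (0.43) without the filter, and the intestinal genes -0.22 (0.02), which without the filter became -0.01 and lay inside that range. Of the genes at least 2-fold higher with ATO in V272M cells, 31 had an R282W log2 ratio within 0.5 of 0, and 8 of them were on the p53 list. SCN1A, a neuronal sodium channel gene, was seen at 3.33 in R282W cells with ATO and at 0.05, 0.01 and 0.02 in the other libraries. PIGY (listed at 0 in all libraries except 9.77 in V272M cells with ATO) and FSBP (3.43, 0.40, 1.85 and 2.17) share 100% of their tiles with other genes and are uncertain.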

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

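The tests of the p53 and mitochondrial patterns below were chosen after the results were seen, and those of the genes listed at 0 before.

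BTG2, a p53 target, had an ATO log2 ratio of 1.93 in V272M cells and -0.56 in R282W cells, opposite directions that each exceed the 0.34 within which 95% of genes differed between the untreated lines. The ATO ratios of 95% of genes lay within 0.69 of 0 in V272M and within 0.67 in R282W cells. By that measure the V272M ratio of BTG2 lay outside and its R282W ratio inside. The difference was not tested for any gene or list in this part, since each ratio rests on 1 library per group.

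The p53 targets as a group had a median ATO log2 ratio of 0.66 in V272M and 0.04 in R282W cells. The mitochondrially encoded genes differed between the lines by a similar median (0.51), and the V272M ATO library also stands apart by its genes listed at 0, both weighed below. A weaker arsenic exposure of the R282W culture is argued against by the 18 NRF2 and metal response genes at least 2-fold higher in V272M cells, whose R282W ratio was a median 0.994 of the V272M ratio (quartiles 0.949 and 1.03), against 0.213 (0.041 and 0.314) for the 14 p53 targets. A scaling difference is argued against by the median of V272M minus R282W ratios over all genes, -0.0067. With 1 library per mutation and treatment, the p53 mutation and not the single culture as the source cannot be told apart, because a line is also 1 infection and 1 culture.

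The 13 mitochondrially encoded genes had a median ATO log2 ratio of 0.21 in V272M cells, 11 of them above 0, and -0.29 in R282W cells, all 13 below 0. A common change in the yield of mitochondrial RNA should set the lines apart by about the same amount in each gene. The V272M minus R282W differences lay above 0 for all 13 genes and ran from 0.26 to 0.70 with an SD of 0.151. An SD between 0.1 and 0.2 decides neither way, so a common change cannot be told apart from changes of single genes. No biological explanation was tested.

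Other genes had opposite ratios, given as V272M and then R282W. IL6ST had 0.35 and -0.71, LAMA2 0.69 and -0.92 and SLC25A21 -0.53 and 0.59. Those that share sequence with other genes and are uncertain were CMTM1 with 0.67 and -0.49, ITIH4 with 0.79 and -0.48, CENPS-CORT with 1.56 and -0.61, EIF3CL with 2.18 and -0.71, HIST1H2AM with -0.68 and 0.65, and CDRT4 with -0.57 and 1.61. All of these were named for their difference between the untreated libraries, which enter both ratios, so opposite ratios follow in part from that choice. With ATO, IL6ST had 12.04 in V272M and 12.66 in R282W cells and LAMA2 2.96 and 2.32.

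The V272M ATO library had the fewest genes listed at 0, 2838 against 3490, 3185 and 3404 in V272M untreated, R282W untreated and R282W ATO, although its steps give it the lowest depth. Rounding of single fragments to 0 in deeper libraries should vanish for transcripts under 3000 bases, yet there it had 2137 zeros, 9.56% fewer than the lowest other library, which argues against it. Olfactory receptor genes above 0, a possible sign of genomic DNA, numbered 184 of 380 against 112, 146 and 132, which is 1.26 times the highest other library, between the bounds of 1.2 and 1.5 set beforehand. Genomic DNA as the cause therefore cannot be told apart from other sources of low signal. The 504 genes above 0 in that library alone had a median value of 0.035, far below the filter.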

How the results depend on the processing

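The removal of sequence-sharing genes and the limma fit without the variance trend were chosen after the data were seen. Numbers of 2-fold genes are given in the order ATO in V272M, ATO in R282W, both lines, untreated lines and lines with ATO (183, 152, 84, 31 and 49 as reported). A pseudocount of 0.1 gave 438, 417, 174, 113 and 176, because genes near 0 then pass. The 1.5-fold threshold gave 969, 916, 457, 145 and 237, and the 4-fold threshold 15, 12, 7, 4 and 4. A filter of 5 left 15 genes between untreated lines and 25 between lines with ATO, and without sequence-sharing genes 7 differed between untreated lines, both from fewer genes compared. The limma count of 3092 (62.8% lower) became 0 with no filter, where 4338 of 18499 genes had an unadjusted p under 0.05 and the prior degrees of freedom dropped to 1.74 from 6.26, and 1629 without the variance trend. The cause was not tested. Median-ratio scaling gave 1412 higher and 1377 lower in place of 1149 and 1943, with 2525 genes shared, and moved the medians of all genes by less than 0.1. The other counts stayed within 1.5 times, r within 0.1, and 20 of 38 list medians outside the central 95% became 19 to 22. Of 602 values of named genes and lists under alternatives, 529 stayed within their spread, 73 moved, 57 of them with a pseudocount of 0.1, and 0 of those called changed sign. The limma fit pairs the libraries by line, and without that term 2451 genes passed, 2450 of them shared. Leaving out a library leaves limma no residual degrees of freedom. Alternatives planned for read counts were not run, since the values are not counts. Depth limits genes near a value of 1, which rest on about 60 to 76 fragments for a transcript of 2000 bases.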

Other observations

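The gene lists in this part were chosen after results were seen, the first because DBP, PER1 and PER2 were among the genes lowest in both lines, so they describe a pattern and do not test it independently. The first holds repressor and output genes of the circadian clock and no activators, so it does not describe the clock as a whole. Of its 11 compared genes all 11 were lower with ATO in both lines, and 9 fell and 0 rose in limma. Since no time is given for the untreated cultures, it is not known whether they were harvested together with the ATO cultures. The list medians were -0.94 in V272M and -1.09 in R282W cells, both at percentile 0 of random lists. CRY1, a clock repressor, was at 0.406 and 0.385 of its untreated value, TEF, a transcription factor related to DBP, at 0.385 and 0.326, and NR1D1 at 0.599 and 0.639. NR1D2, at 0.904 and 0.961, did not pass (limma adjusted p = 0.321). Of the activators, ARNTL (BMAL1) was 1.31-fold and 1.73-fold higher (limma adjusted p = 0.0135), CLOCK at 0.779 and 0.737 (0.0141) and NPAS2, which did not pass (0.133), at 0.886 and 0.832.

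Lists of autophagy, iron and glutathione genes were also compared. Of 9 autophagy genes 8 rose and 0 fell, with medians of 0.75 and 0.80. SQSTM1 (p62) was 2.26-fold and 2.21-fold higher and MAP1LC3B (LC3B) went from 55.92 to 119 and from 49.07 to 122.8. The level of SQSTM1 is uncertain, since 20.7% of its exonic bases overlap MRNIP on the opposite strand. MRNIP had at most 12.04, too low to supply the rise of SQSTM1. That rise was from 129.05 to 292.11 in V272M and from 117.37 to 259.53 in R282W cells. Of 14 iron and heme genes 7 rose and 1 fell (BLVRA), and 4 were lower in both lines, with medians of 0.16 and 0.15. Some that rose, FTH1, FTL and BLVRB among them, were also on the list of NRF2 targets. The ferritin subunits FTH1 and FTL were 3.02-fold and 2.77-fold higher in V272M cells and 3.02-fold and 2.77-fold in R282W cells, which made FTH1 the highest gene of both ATO libraries, and ALAS1, the first enzyme of heme synthesis, was 2.31-fold and 2.05-fold higher. The level of FTH1 is uncertain, since 62.4% of its exonic bases overlap BEST1 on the opposite strand. BEST1 had at most 4.10, too low to supply the rise of FTH1. That rise was from 3570.06 to 10786.36 in V272M and from 3438.94 to 10389.02 in R282W cells. Of 10 glutathione and cystine genes 8 rose and 1 fell (GPX4, at 0.685 and 0.717), with medians of 0.42 and 0.61. Among those that rose, GCLC, GCLM, GSR and SLC7A11 were also on the NRF2 list. CHAC1, SLC3A2 and SLC7A11 were also on the ATF4 list, so these rises are largely the ones already described. Replication-dependent histone genes, many of which share sequence, had medians of -0.35 in V272M and -0.03 in R282W cells over 29 genes. Of these, 8 fell and 1 rose. Most of the 29 stayed under 5 in every library. Many are also short, and at a given value a shorter transcript rests on fewer fragments. HIST1H4D, counted among those that fell, went from 1.43 to 0.25 in V272M and from 0.85 to 0.22 in R282W cells. These medians and counts therefore carry much counting error, and the lower median in V272M cells is uncertain. The gene that rose, HIST2H2AA3, shares 100% of its tiles and was listed at 0 in untreated R282W cells, so it is uncertain. Among those that fell, HIST2H2AA4 (95.2% of tiles shared), HIST1H4J (84.6%) and HIST2H2AC (28.6%) are uncertain in the same way.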
